A study of Mus musculus with 3 samples.

How the data were processed

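Glandular stomachs (hindstomachs) of mouse embryos at E18.5 were dissociated with trypsin and DNase I, red blood cells were lysed, and single cells were captured in droplets with the DNBelab C Series kit, which tags the 3′ end of each messenger RNA with a cell barcode and a unique molecular identifier (UMI). The 3 libraries carry Shh-Cre alone (control), Shh-Cre with YAP5SA, and Shh-Cre with both Yap alleles floxed (Yap knockout). Shh-Cre is a recombinase expressed in the stomach epithelium, and YAP5SA is a form of YAP whose inhibitory phosphorylation sites are mutated, so that it stays active. Each genotype is represented by 1 library, and how many embryos went into each is not given in the sources used here. Organoid bulk RNA sequencing from the same study is not analysed here.

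The deposited values are counts: whole numbers of UMIs per gene and cell, written by PISA 1.0 per the file headers, with STAR alignment and the GRCm39 mouse genome per the submitters' processing notes. No normalisation had been applied. Cells with fewer than 1000 UMIs are absent from the deposited matrices, and the genes are given by symbol without a stated annotation release, so no coordinates are reported. A free-RNA correction is not stated. The control library held 7692 cells and 48910624 UMIs, the YAP5SA library 9439 cells and 65843656 UMIs, and the Yap knockout library 5739 cells and 40857356 UMIs.

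Cells with at least 500 detected genes and at most 20% of UMIs from mitochondrial genes passed, which left 7372 control, 9029 YAP5SA and 5201 Yap knockout cells. Doublets were scored in each library by Scrublet in scanpy 1.11.5 with an expected rate of 0.06. Its own threshold called 0 cells in each library, so the fallback fixed beforehand was used and cells with the highest 6% of scores were removed (413, 511 and 311 cells, fewer than 6% where scores were tied). The kept set held 6959 control, 8518 YAP5SA and 4890 Yap knockout cells. All kept cells were clustered together without batch integration: counts were scaled to 10000 per cell and log-transformed, 3000 variable genes and 40 principal components were used, and Leiden clusters (igraph 0.11.9) were found at resolution 1.0 on 15 neighbours. Cells of epithelial clusters were clustered again with 2000 variable genes and 30 components.

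Clusters were named from 17 broad and 9 epithelial marker classes fixed beforehand. Each cluster's CPM was set against the mean of the other clusters, and the cluster took the class with the most markers among its 10 leading genes (at 20 CPM or more), with ties broken by the mean log2 fold of the markers. It stayed unnamed with fewer than 3 markers raised at least 2-fold, with a mean marker log2 fold under 0.5, or with a median depth far under that of the library and no leading marker. The limit of that last rule lay just below the depth of the shallow pit-like subcluster found without the fixed genes, at 0.3398 of the library median. These cutoffs for a name were set after the clusters had been seen. Clusters with an epithelial subclass name were counted as epithelial-like.

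UMIs were summed over the cells of a class in each library and scaled to CPM, a gene's UMIs over all UMIs of the sum times 10 to the power 6. The ratio of YAP5SA or Yap knockout to control was given with the exact conditional 95% interval of a pair of Poisson counts, and shares of cells with exact Clopper-Pearson 95% intervals. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the class sum and written as a lower bound. Intervals and floors cover counting error only. With 1 library per genotype no test between genotypes was possible, and no p-value or count of changed genes is given. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and anndata 0.12.19, and plots were drawn with matplotlib 3.10.9.

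The samples, comparisons, gene lists, marker genes, rule for named genes and main set of alternative settings were fixed before the data were examined. In epithelial-like cells, the named genes are the 10 highest and 10 lowest by the log2 ratio with a pseudocount of 5 CPM, among genes with at least 50 CPM in either library. Mitochondrial, ribosomal protein, haemoglobin, Xist, Tsix, Y-linked and predicted genes were left out. For fibroblast-like, smooth muscle-like and macrophage-like cells, the 5 highest and 5 lowest were named by the same rule. Enteric glia-like cells and interstitial cells of Cajal also had at least 200 cells in every library, but only their list medians were read. For each list, up to 2 members with the highest and 2 with the lowest ratio could be named, and a fixed set of genes was always read: Yap1, Ccn1, Ccn2, Ankrd1, Amotl2, Ajuba, Lats2, Muc5ac, Gkn1, Gkn2, Tff1, Tff2, Muc6, Pgc, Atp4a, Atp4b, Chga, Ghrl, Sox2, Sox9, Lgr5, Cdx2, Clu, Ly6a and Mki67.

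The 29 fixed lists covered YAP/TEAD targets, Hippo components, fetal and regenerative epithelium, pit, neck and chief, parietal and enteroendocrine cells, gastric transcription factors, stem and progenitor genes, squamous and intestinal epithelium, Wnt, Notch, Hedgehog and BMP, and ErbB signalling, DNA replication and mitosis, adhesion and basement membrane, actin cytoskeleton, inflammatory cytokines, interferon, p53, dissociation stress, the unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, mucus secretion, stromal collagen and matrix, and smooth muscle. A list median is the median log2 ratio over members with at least 10 CPM in either library, given where at least 5 members were measured. Its percentile among 10000 random lists of the same size, matched in 20 expression bins, describes these libraries and is not a test between genotypes. Counting intervals of list medians came from 2000 Poisson redraws.

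The ratio and list calculations were tested on simulated data made from the control epithelial sum, with 9374 genes at the depths of each comparison. Intervals of unchanged genes held the true ratio in 95.5% of genes for either comparison. Genes set 4-fold higher were read at a median of 4.03-fold at the depths of both comparisons. Of lists of 20 unchanged genes, 5% fell outside the random interval at the YAP5SA depths and 3% at the Yap knockout depths, and 100% of lists set 2-fold higher lay above it.

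The alternative settings of that set were at least 1000 detected genes, at most 10% mitochondrial UMIs, doublets kept, resolution 0.5, each library clustered alone, TMM scaling from edgeR 4.0.16 in R 4.3.3, the mean over cells in place of the sum, cells thinned to 2000 UMIs, a pseudocount of 1 without the low-level filter, an epithelial marker gate, and the largest shared epithelial subclass. Chosen after seeing the data were 7 more. Some left out cells: squamous-like and intestinal-like cells, cycling-like cells for the DNA replication list, or low-count subclusters for list medians and shares. Others were subclass shares clustered without the fixed genes, doublets kept but placed in the existing clusters, and fibroblast-like cells joined with the unnamed stromal cluster. The last was subtraction of the non-epithelial profile, scaled to the summed Col1a1, Col1a2 and Col3a1, with negative values set to 0. It was partial: Col1a1 still stood at 911.5 CPM in the control, 379.1 in YAP5SA and 75.95 in the Yap knockout.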

Results

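Single-cell RNA sequencing of the E18.5 mouse glandular stomach was compared between 3 libraries, a Shh-Cre control, Shh-Cre with constitutively active YAP (YAP5SA) and a Shh-Cre Yap knockout. YAP, encoded by Yap1, is the coactivator held in check by the Hippo pathway, which acts on genes through TEAD factors. The question the comparison addresses is how the stomach epithelium differs between YAP activity states. After filtering, the median depth was 4900 UMIs per cell in 6959 control cells, 5224.5 in 8518 YAP5SA cells and 4979.5 in 4890 Yap knockout cells. Since each genotype has 1 library, no difference below has a replicate check, and every interval covers counting error only.

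Yap1 itself was read first. In epithelial-like cells it stood at 47.0 CPM in the control, 55.2 in YAP5SA and 23.0 in the Yap knockout, so it was 2.04-fold (1.68 to 2.49) lower in the knockout and 1.17-fold (1.01 to 1.37) higher in YAP5SA. In non-epithelial cells of the same libraries it stood at 54.0, 54.2 and 49.5 CPM. A 3′ tag that lies outside the deleted exon would not report the deletion, and a human YAP5SA transgene would not be counted under the mouse gene. The Yap1 level therefore does not measure how complete the deletion or how strong the overexpression was.

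The dissociated tissue held epithelium, stroma, muscle, nerve and blood cells in different proportions in the 3 libraries. Epithelial-like cells made up 13.6% (12.8 to 14.5) of control cells, 21.2% (20.3 to 22.04) of YAP5SA cells and 28.0% (26.8 to 29.3) of Yap knockout cells. Fibroblast-like cells made up 45.8% (44.6 to 47.0) of the control, 14.1% (13.4 to 14.9) of YAP5SA and 10.7% (9.88 to 11.6) of the Yap knockout. A further 23.6% of YAP5SA cells and 0.0718% of control cells lay in a stromal cluster without a name. Fibroblast was its next class under the naming rule, so the fibroblast-like share of YAP5SA depends on where this cluster is counted. Macrophage-like cells were 13.2% (12.5 to 13.9) of YAP5SA against 5.63% (5.10 to 6.20) of the control, and neutrophil-like cells 3.05% (2.70 to 3.44) against 0.273% (0.165 to 0.426). Enteric neuron-like cells were 10.0% (9.21 to 10.9) of the Yap knockout against 2.01% (1.70 to 2.37) of the control, and enteric glia-like cells 10.3% (9.43 to 11.2) against 5.26% (4.75 to 5.81).

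Several classes were made of different clusters in different libraries. Control and Yap knockout epithelial-like cells lay mostly in clusters 9, 10 and 12, whereas 1514 of the 1802 YAP5SA epithelial-like cells lay in cluster 13, which held 3 control cells. Macrophage-like cells came from cluster 6, with 324 control, 774 YAP5SA and 224 Yap knockout cells, and cluster 22, led by antigen-presentation genes, with 68, 350 and 179. Smooth muscle-like cells of the control and YAP5SA lay mostly in cluster 8 and those of the Yap knockout mostly in cluster 17, which held 644 of them. Neither the yield of each layer in trypsin nor the effect of red-cell lysis on these shares was measured. When predicted doublets were kept and the cells clustered anew, the YAP5SA epithelial cluster lost its name. Its 1605 YAP5SA cells were then not counted, and the epithelial-like share of YAP5SA was 3.49% against 13.4% in the control.

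**Figure D1:**
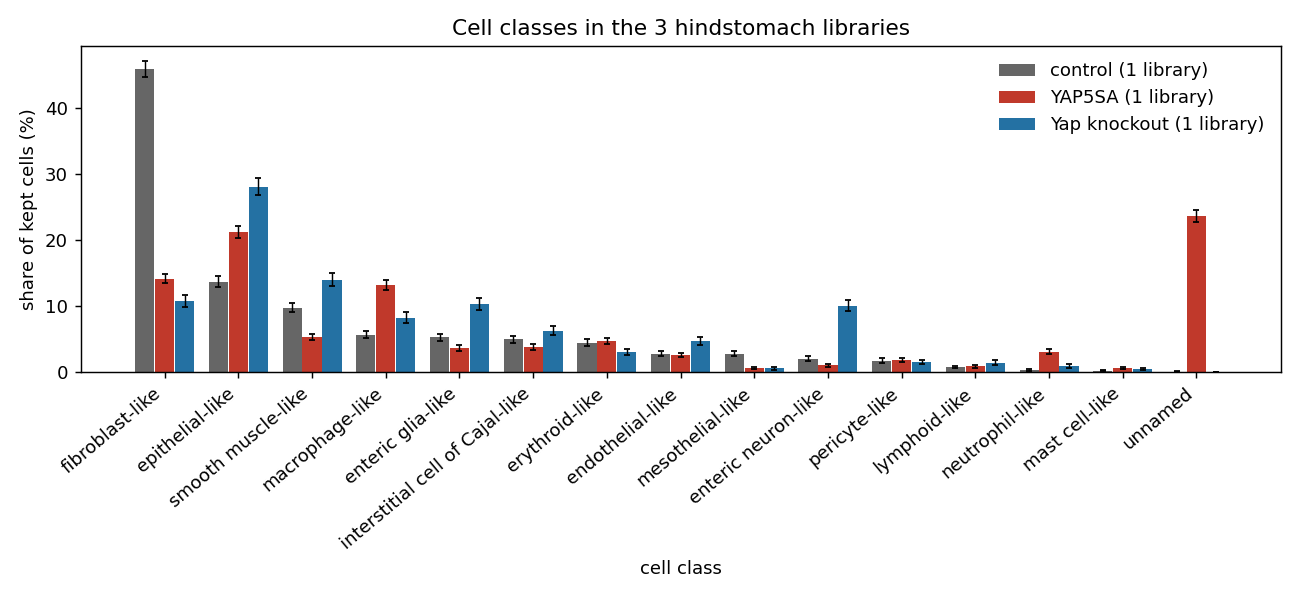
Share of kept cells in each class (percent, linear axis from 0) for the control, YAP5SA and Yap knockout libraries, with exact 95% intervals as error bars. Fibroblast-like cells stand at 45.8% of the control, 14.1% of YAP5SA and 10.7% of the Yap knockout, without the unnamed stromal cluster.

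In the YAP5SA epithelium, genes of the secretory gastric lineages were far lower than in the control and YAP/TEAD targets, fetal and regenerative epithelium genes and glycolysis genes were higher. Msln, which encodes the surface glycoprotein mesothelin, stood at 1394 CPM against 40.3, 34.6-fold (29.9 to 40.2) higher. Ankrd1, a direct YAP target, stood at 123 CPM against 0 counts in the control, at least 189-fold higher. Pga5, which encodes a pepsinogen, stood at 164 CPM against 16790, 102-fold (98.8 to 106) lower. Tff1, the trefoil peptide of surface mucous cells, stood at 72.1 CPM against 6469, 89.8-fold (84.9 to 94.99) lower.

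The other genes with the highest ratios included secreted and membrane proteins of embryonic and barrier epithelia. Wnt7b, a secreted Wnt ligand, was 131-fold (51.2 to 482) higher, from 4 control UMIs. Lcn2, an iron-siderophore binding protein of inflamed epithelia, was 47.7-fold (32.5 to 73.0) higher and the neuronal-type glucose transporter Slc2a3 42.5-fold (29.9 to 62.6). The embryonic tight junction protein Cldn6 was 35.7-fold (22.8 to 59.4) higher, the annexin Anxa8 28.6-fold (20.3 to 41.5), the chloride channel family member Clic3 25.8-fold (20.5 to 32.8) and the uroplakin Upk1b 25.3-fold (17.6 to 37.8). Alb, the gene of serum albumin, was 123-fold (42.1 to 598) higher, from 3 control UMIs. It was a leading gene of the unnamed subcluster 12, with 379 YAP5SA cells, next to the liver genes Ahsg, Apoa2 and Fgb, and of the intestinal-like cluster 24. With each library clustered alone, YAP5SA gave 31 hepatocyte-like and 0 intestinal-like cells. In non-epithelial cells, where free RNA of the epithelium is also counted, Msln stood at 83.9 CPM in YAP5SA against 28.8 in the control, Lcn2 at 163 against 15.9 and Upk1b at 13.2 against 10.2.

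The other genes with the lowest ratios included acid-pump, digestive and mucous secretion genes of the stomach. Both proton pump subunits were among them, Atp4b at 272-fold (202 to 373) and Atp4a at 163-fold (126 to 215) lower. Smim38 was 215-fold (135 to 364) lower, the secreted phospholipase Pla2g1b 89.8-fold (72.8 to 112), the pepsinogen Pgc 82.6-fold (71.2 to 96.2), the colipase Clps 72.4-fold (66.2 to 79.2), the gel-forming mucin Muc5b 69.8-fold (61.9 to 79.1) and the secreted protein Bpifb1 55.1-fold (53.1 to 57.1). These RNAs were also found at low levels outside the epithelium, with Pga5 at 415 CPM in control and 18.0 in YAP5SA non-epithelial cells. TMM scaling moved the median of all genes in this comparison by 0.14 on the log2 scale, from 0.08 to 0.22, so log2 ratios near 0 carry no direction.

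Targets of YAP and TEAD were higher as a group in the YAP5SA epithelium. Of 21 measured members 18 were higher, with a list median of 1.14 on the log2 scale, above 100% of matched random lists, against 0.13 in non-epithelial cells. Ccn2, a matricellular protein, was 13.9-fold (10.9 to 18.1) higher and its relative Ccn1 2.10-fold (1.94 to 2.27). The scaffold gene Amotl2 was 2.51-fold (2.15 to 2.93) higher, the LIM protein gene Ajuba 9.51-fold (6.80 to 13.7) and the Hippo kinase gene Lats2 2.24-fold. Hippo components had a median of 0.28 with 15 of 22 higher (percentile 87.6), among them the transcription factor Tead4 at 28.0-fold (12.8 to 76.5). Fetal and regenerative epithelium genes had a median of 1.47 with 18 of 19 higher (percentile 100), and Msln had the highest ratio among them. Clu was 1.41-fold (1.37 to 1.46) higher and Ly6a 7.84-fold (3.92 to 18.4). The fetal list was also higher in non-epithelial cells, at 0.97.

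All measured pit, parietal and intestinal genes were lower in the YAP5SA epithelium. The pit list had a median of -1.86 (11 of 11 lower, percentile 0), with Gkn1, a secreted gastrokine, 170-fold (111 to 276) lower. Gkn2 was 692-fold (236 to 3368) lower, from 3 YAP5SA UMIs, and the mucin Muc5ac 29.5-fold (11.6 to 95.9). Neck and chief cell genes had a median of -3.90 (7 of 8 lower, percentile 0), with the trefoil gene Tff2 14.3-fold and the mucin gene Muc6 7.75-fold lower. The exception was Wfdc2, a secreted protease-inhibitor family member, which was 8.16-fold higher. Parietal genes had a median of -2.27 (7 of 7 lower, percentile 0) and intestinal genes -1.71 (10 of 10 lower, percentile 0). Of the enteroendocrine list only 4 members were measured, which gives no median. Chga, a granule protein, was 19.6-fold (11.7 to 34.5) lower and Ghrl, the ghrelin gene, 8.61-fold lower.

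Among identity factors the picture was mixed. Gastric transcription factors had a median of -0.51 (10 of 15 lower, percentile 0.11), with Nkx6-3 11.9-fold and the goblet and mucous factor Spdef 7.35-fold lower. Sox2, the foregut factor, stood at 19.9 CPM against 16.3, a ratio of 1.22 (0.947 to 1.58) that this depth does not separate from 1, and the same holds for the intestinal factor Cdx2 at 1.07 against 1.96 CPM. Stem and progenitor genes had a median of -0.55 (8 of 11 lower, percentile 0.29), with Lgr5 13.9-fold (8.59 to 23.5) and Sox9 2.59-fold lower. Squamous epithelium genes had a median of 0.79 (5 of 9 higher, percentile 99.2), with Krt14 9.74-fold and Krt4 6.18-fold higher, and 0.39 in non-epithelial cells. Both keratins stood mainly in the squamous-like cells of YAP5SA, Krt14 at 513 CPM against 20.4 in its other epithelial-like cells and Krt4 at 2873 against 263. With squamous-like and intestinal-like cells of both libraries left out, the list median was 1.90 over 6 genes. Mucus secretion genes had a median of -1.60 (10 of 14 lower, percentile 0), with the mucin-folding enzyme Agr2 26.2-fold lower.

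Every measured DNA replication and mitosis gene was higher in the YAP5SA epithelium. The list had a median of 0.83 (28 of 28 higher, percentile 100) against -0.03 in non-epithelial cells. A cycling-like subcluster of deep cells, with a median of 10380 UMIs, held 408 of 1802 YAP5SA, 0 control and 1 Yap knockout epithelial-like cells. Without it the median was 0.55 (percentile 99.99). With predicted doublets kept and the cells clustered anew it was 0.15, but there the main YAP5SA epithelial cluster had lost its name and was left out. The size of this class depended on the clustering, with 163 of 1771 YAP5SA cells when each library was clustered alone and 1118 of 1803 at resolution 0.5. YAP5SA epithelial-like cells clustered apart from the control, so 0 control cells does not show that the control held no dividing cells. Among all epithelial-like cells the ribonucleotide reductase gene Rrm2 was 4.21-fold, the mitotic kinase gene Cdk1 3.16-fold and Mki67 1.37-fold higher. Glycolysis and hypoxia genes had a median of 1.17 (16 of 18 higher, percentile 100), with the glucose transporter gene Slc2a1 10.9-fold and the enolase gene Eno1 4.44-fold higher, whereas oxidative phosphorylation genes had a median of -0.46 (15 of 21 lower, percentile 0.10). Cholesterol synthesis genes had a median of 0.49 (13 of 16 higher, percentile 98.4). Adhesion and basement membrane genes had a median of 0.54 (14 of 18 higher, percentile 97.6) and actin cytoskeleton genes 0.63 (15 of 22 higher, percentile 99.5). Inflammatory cytokine genes had a median of 1.19 (13 of 16 higher, percentile 100), with the chemokine Cxcl5 at 41.1 CPM against 0 counts, at least 62.9-fold higher, and the same list stood at 1.02 in non-epithelial cells.

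Hedgehog and BMP genes had a median of -0.59 (11 of 13 lower, percentile 0.08), with the epithelial ligand gene Ihh 5.03-fold lower. Wnt targets had a median of 0.33 (7 of 11 higher, percentile 86.9), ErbB ligands and feedback genes 0.35 (8 of 13 higher, percentile 92.2) and Notch genes 0.11 (4 of 7 higher, percentile 57.9). The p53 list stood at 0.50 (9 of 11 higher, percentile 95.5), the interferon list at -0.69 (6 of 8 lower, percentile 0.28) and the unfolded protein response at -0.45 (11 of 13 lower, percentile 0.54). Dissociation and heat stress genes, induced by tissue handling, stood at -0.41 (11 of 17 lower, percentile 0.70). Collagen and stromal matrix genes, which mark RNA of other cells, stood at -1.32 (18 of 19 lower, percentile 0) and smooth muscle genes at -0.95 (13 of 14 lower, percentile 0). Measured by collagen, RNA of non-epithelial cells would account for up to 44.5% of the control epithelial sum, 28.5% of YAP5SA and 28.5% of the Yap knockout. With that profile subtracted, the YAP/TEAD median was 2.69 and the DNA replication median 1.54. The subtraction still left Col1a1 at 911.5 CPM in the control and 379.1 in YAP5SA.

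**Figure D2:**
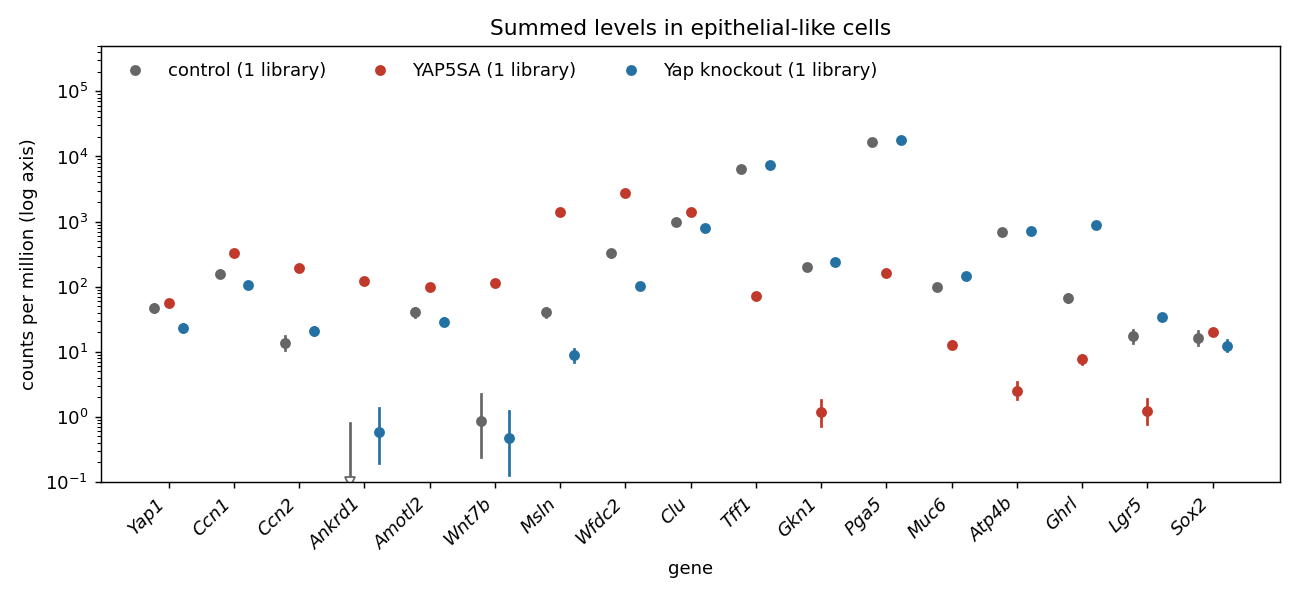
Level of 17 genes in epithelial-like cells of the control, YAP5SA and Yap knockout libraries (CPM, log axis), with exact 95% Poisson intervals and open triangles for 0 counts. Tff1 and Pga5 stand at 72.1 and 164 CPM in YAP5SA against 6469 and 16790 in the control, and Msln at 1394 against 40.3.

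Named subclusters of the epithelium followed the same division. Unnamed subclusters held 58.5% of control, 64.7% of YAP5SA and 49.7% of Yap knockout epithelial-like cells, so the shares below leave these cells without a type. Subcluster 0, unnamed and led by Pga5, held 345 control, 24 YAP5SA and 146 Yap knockout cells. The unnamed subclusters 5, 11 and 12 held 415, 283 and 379 YAP5SA cells, and 0, 2 and 1 control cells. Pit-like cells were 171 of 949 control, 2 of 1802 YAP5SA and 125 of 1371 Yap knockout epithelial-like cells, 18.0% (15.6 to 20.6), 0.111% (0.0134 to 0.400) and 9.12% (7.65 to 10.8). With at most 10% mitochondrial UMIs the order of control and Yap knockout turned, at 12.2% and 14.2%. Since pit genes differ between the libraries, the cells were also clustered without any fixed gene, after which 56.1% of control, 2.78% of YAP5SA and 10.9% of Yap knockout cells were pit-like. Of these, 319 control, 31 YAP5SA and 68 Yap knockout cells lay in a shallow subcluster with a median of 1678 UMIs and no pit marker among its leading genes, and 213, 19 and 81 cells in a subcluster led by Gkn2, Tff1 and Gkn1. Squamous-like cells, the type of the neighbouring forestomach, were 178 YAP5SA, 21 control and 5 Yap knockout cells, and 167, 21 and 5 without the fixed genes. Parietal-like cells were 58 control, 3 YAP5SA and 165 Yap knockout cells, and 43, 4 and 183 without them. Enteroendocrine-like cells were 15, 4 and 44, and 17, 4 and 44 without them. Neck-like cells were 98, 10 and 299 cells, but 276, 17 and 27 without the fixed genes, where 16, 5 and 326 cells were chief-like. Unnamed subclusters of shallow cells (6, 7 and 14) held 201, 6 and 0 control cells, 27, 4 and 34 YAP5SA cells and 345, 190 and 0 Yap knockout cells. The median depth of epithelial-like cells was 2474 UMIs in the control, 6269 in YAP5SA and 2637 in the Yap knockout.

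In the Yap knockout epithelium, hormone and intestinal lipid-handling genes were higher than in the control, and squamous keratin and collagen genes were lower. Ghrl stood at 889 CPM against 65.8, 13.5-fold (12.1 to 15.2) higher. The somatostatin gene Sst stood at 110 CPM against 5.23, 21.0-fold (14.0 to 33.0) higher, and the gastrin gene Gast at 64.2 against 3.70, 17.3-fold (10.7 to 29.99). These hormone genes led a subcluster with 15 control and 44 Yap knockout cells, and the intervals do not cover the sampling of so few cells. Krt15, a keratin of stratified epithelia, stood at 22.9 CPM against 305, 13.3-fold (11.4 to 15.6) lower. Of the gastric genes that were far lower in YAP5SA, Tff1 was 1.13-fold (1.11 to 1.14), Pga5 1.08-fold (1.07 to 1.09) and Clps 1.63-fold higher, whereas Smim38 was 1.64-fold, Muc5b 1.57-fold and Bpifb1 1.38-fold lower. With non-epithelial RNA subtracted, Tff1 and Pga5 turned to log2 ratios of -0.12 and -0.18. Clps then stood at 0.40, and Smim38, Muc5b and Bpifb1 stayed lower.

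The other genes with the highest ratios encode proteins of the small intestine. Apoa4, an apolipoprotein of enterocytes, was 7.22-fold (6.89 to 7.57) higher, Apoc2 13.1-fold (11.4 to 14.9) and Apoc3 11.8-fold (10.3 to 13.5). The intestinal trefoil gene Tff3 was 14.0-fold (11.3 to 17.4) higher, the fatty acid binding protein genes Fabp2 11.3-fold (9.62 to 13.3) and Fabp1 7.53-fold (6.70 to 8.50), and the retinol binding protein gene Rbp2 5.51-fold (5.01 to 6.08). In non-epithelial cells Ghrl was 4.599-fold, Apoa4 4.09-fold, Tff3 6.58-fold and Gast 6.92-fold higher as well, and Sst 0.943-fold. With squamous-like and intestinal-like cells left out, the intestinal list median was 0.32 in place of 1.22.

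Genes with the lowest ratios included keratins and stromal genes. Krt5 was 22.1-fold (14.0 to 36.9) and Krt4 20.4-fold (14.7 to 29.1) lower, Upk3bl 21.4-fold (15.5 to 30.2), the iron-binding lactoferrin gene Ltf 33.4-fold (19.6 to 62.0) and the carbonyl reductase gene Cbr2 8.85-fold (7.22 to 10.9). The collagen genes Col1a1 and Col1a2 were 8.29-fold (8.05 to 8.55) and 6.84-fold (6.50 to 7.20) lower, with Plac9 at 8.84-fold (7.70 to 10.2) and Dlk1 at 6.33-fold (5.87 to 6.82). Col1a1 also stood at 1977 CPM against 10320 in non-epithelial cells, which held fewer fibroblast-like cells, and at 9041 against 15890 in fibroblast-like cells.

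YAP/TEAD targets had a list median of -0.29 in the Yap knockout epithelium (13 of 18 lower, percentile 0.04) against 0.14 in non-epithelial cells. Their direction differed by gene: Ccn1 was 1.49-fold (1.35 to 1.65) lower, Amotl2 1.38-fold, Ajuba 2.22-fold and the receptor kinase gene Axl 2.88-fold (2.29 to 3.63) lower, whereas Ccn2 was 1.51-fold (1.13 to 2.05) higher. Ankrd1 had 5 UMIs in the Yap knockout and 0 in the control, and Lats2 was 1.31-fold (0.956 to 1.78) lower. After thinning to 2000 UMIs per cell the median was -0.02, and after subtraction of non-epithelial RNA -0.10, both inside the interval of matched random lists, but the subtraction left 11 of 18 members and moved Ccn1 to -1.16 and Amotl2 to -1.04. Fetal and regenerative genes had a median of -0.41 (13 of 17 lower, percentile 0), with Msln 4.59-fold and Clu 1.25-fold lower. Ly6a was too shallow to separate, at a ratio of 1.70 (0.745 to 4.37).

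Before subtraction of non-epithelial RNA, differentiated gastric lists stood near or slightly above the control. Parietal genes had a median of 0.49 (7 of 8 higher, percentile 99.9), with the chloride transporter gene Slc26a9 2.38-fold and Atp4a 1.56-fold higher and Atp4b at 1.03-fold (0.990 to 1.08). After subtraction the parietal median was 0.26 (percentile 89.3), with Atp4a at 0.35 and Atp4b at -0.25. Pit genes had a median of 0.21 (8 of 12 higher, percentile 98.4), with the claudin gene Cldn18 1.93-fold, Muc5ac 1.74-fold, Gkn2 1.76-fold and Gkn1 1.20-fold higher. That median turned to -0.36 as a mean over cells, -0.25 after thinning and -0.07 after subtraction. Neck and chief genes stood at -0.10 (5 of 9 lower, percentile 37.1), with Muc6 1.47-fold and Pgc 1.18-fold higher, and Tff2 1.62-fold and the intrinsic factor gene Cblif 2.51-fold lower. After subtraction the neck and chief median was -0.34 (percentile 2.27), and Pgc turned to a log2 ratio of -0.06. Enteroendocrine genes had a median of 1.12 (6 of 7 higher, percentile 100), with Chga 2.48-fold higher, beside 1.21 in non-epithelial cells, which include enteric neurons. Intestinal genes had a median of 1.22 (9 of 11 higher, percentile 100), beside 51 intestinal-like cells of 1371 in the Yap knockout (3.72%) and 31 of 949 in the control (3.27%). Squamous genes had a median of -2.39 (8 of 8 lower, percentile 0), beside 5 squamous-like cells of 1371 in the Yap knockout and 21 of 949 in the control. With squamous-like and intestinal-like cells left out, too few squamous genes were measured for a median.

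Gastric transcription factors stood at 0.15 (10 of 15 higher, percentile 83.6), with Hnf4a 2.06-fold higher. Stem and progenitor genes stood at 0.22 (7 of 12 higher, percentile 93.2), with Lgr5 at 34.4 CPM against 17.2 (ratio interval 1.55 to 2.60) and Sox9 at a ratio of 0.869 (0.755 to 1.00). Sox2 had a ratio of 0.756 (0.556 to 1.03), and Cdx2 was 2.66-fold (1.28 to 6.21) higher. DNA replication and mitosis genes had a median of -0.29 (25 of 28 lower, percentile 0), with Dut and Ccna2 each 1.64-fold lower, and Mki67 at 1.06-fold (0.879 to 1.27). With non-epithelial RNA subtracted, the DNA replication median was -0.06 (percentile 1.61). The mucus list stood at 0.04 (7 of 14 higher, percentile 53.8), cholesterol synthesis at 0.04 (9 of 16, percentile 52.7), Hippo components at 0.04 (11 of 20, percentile 40.8) and Wnt targets at 0.03 (5 of 9, percentile 38.5). Each of these last medians turned sign under TMM scaling.

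Of the remaining lists, ErbB ligands and feedback stood at 0.42 (9 of 14 higher, percentile 99.8), with the phosphatase gene Dusp4 3.90-fold higher, the unfolded protein response at 0.28 (9 of 14 higher, percentile 99.7) and the p53 list at 0.30 (7 of 12 higher, percentile 98.6). Hedgehog and BMP genes stood at -0.25 (10 of 13 lower, percentile 0.62) and Notch genes at -0.25 (4 of 7 lower, percentile 1.67). With non-epithelial RNA subtracted, Notch genes stood at 0.01. Dissociation and heat stress genes stood at -0.35 (13 of 17 lower, percentile 0.04), and at -0.34 in non-epithelial cells, but at 0.14 with non-epithelial RNA subtracted. Adhesion genes stood at -0.17 (9 of 17 lower, percentile 7.45), actin genes at -0.15 (14 of 22 lower, percentile 10.7) and glycolysis genes at -0.07 (10 of 17 lower, percentile 34.9). Subtraction turned adhesion to 0.11 and actin to 0.34. Inflammatory genes stood at a median of -0.09 with a mean of 0.21 (percentile 9.94), interferon genes at 0.15 with a mean of -0.06 (percentile 70.0) and oxidative phosphorylation genes at 0.00 (percentile 77.4). Collagen and matrix genes stood at -1.82 (19 of 19 lower, percentile 0), and at -1.55 in non-epithelial cells. Smooth muscle genes stood at -0.12 (12 of 14 lower, percentile 21.9).

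**Figure D3:**
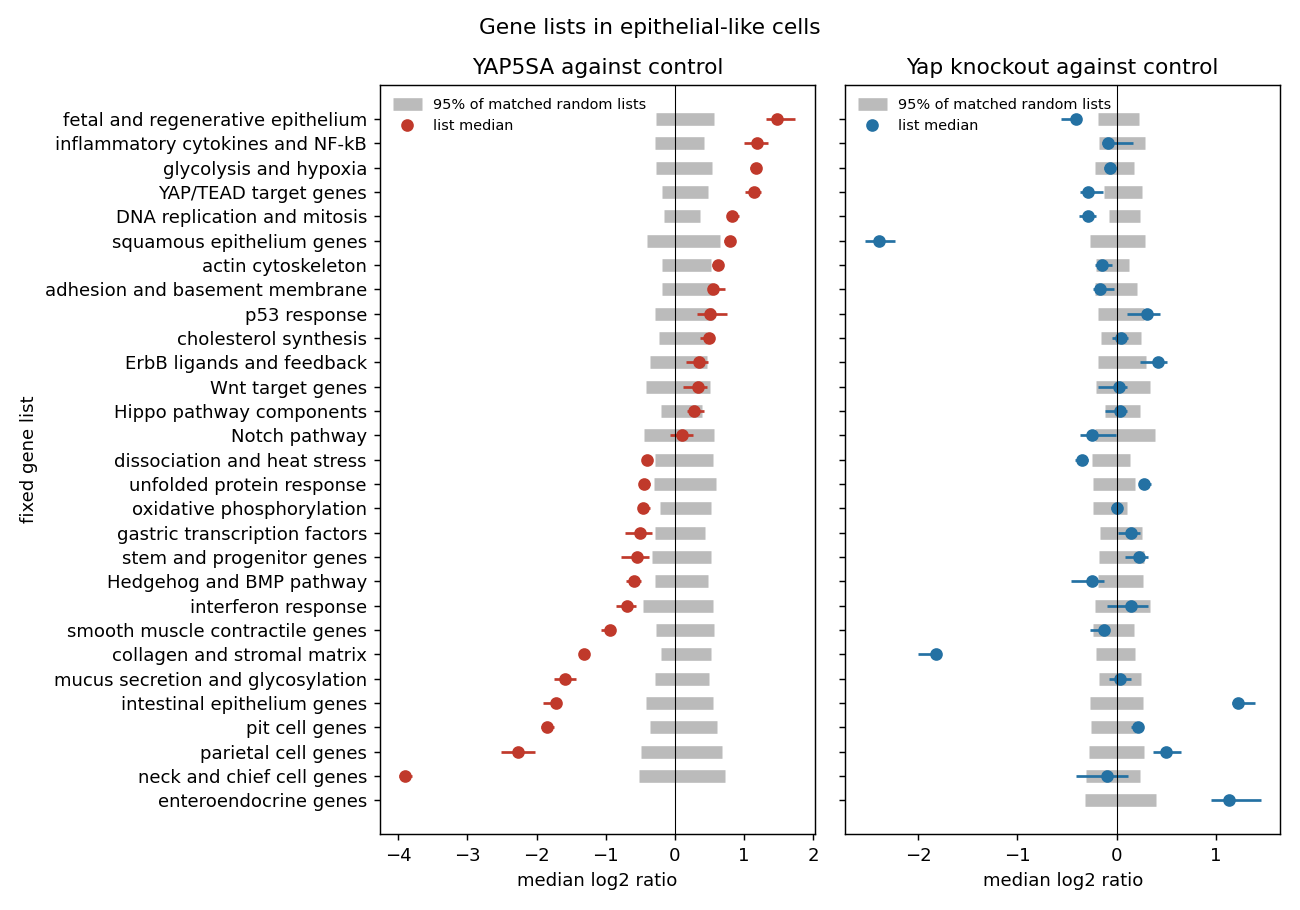
Median log2 ratio to control of each fixed gene list in epithelial-like cells, with YAP5SA and the Yap knockout in separate panels. Points are medians, coloured lines their 95% counting intervals and grey bars the central 95% of matched random lists; the neck and chief list stands at -3.90 and the YAP/TEAD list at 1.14 in YAP5SA.

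Set directly against the Yap knockout, the YAP5SA epithelium differed most in the gastric and intestinal lists. YAP/TEAD targets had a median of 1.63 and DNA replication genes 1.10, both above 100% of random lists, with fetal and regenerative genes at 1.67, glycolysis genes at 1.32 and squamous genes at 1.98. Pit genes stood at -2.06, enteroendocrine genes at -2.50, parietal genes at -2.82, neck and chief genes at -3.08 and intestinal genes at -3.21. Yap1 was 2.40-fold higher in YAP5SA than in the Yap knockout.

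Shh-Cre acts in the epithelium, and many of the highest and lowest ratios in stromal and immune cells were those of epithelial transcripts that followed the epithelium of the same library. In YAP5SA fibroblast-like cells Msln was 15.7-fold (12.6 to 19.8), Wfdc2 8.72-fold, Krt4 8.06-fold, Krt7 7.93-fold and Krt19 6.28-fold higher, whereas Pga5 was 18.9-fold, Muc5b 14.9-fold, Bpifb1 12.7-fold and Tff1 11.4-fold lower. The fifth lowest was Fgf14, a fibroblast growth factor family gene, at 2.62-fold (2.19 to 3.17). Smooth muscle-like cells had the same epithelial genes at both ends, with Msln 21.96-fold and Krt7 7.71-fold higher and Pga5 29.5-fold lower, and in addition the neutrophil alarmin gene S100a9 6.82-fold higher and the matrix gene Npnt 3.66-fold (3.32 to 4.04) lower. In macrophage-like cells Mpo, the neutrophil myeloperoxidase, stood at 116 CPM against 0 counts, at least 91.9-fold higher, and the neutrophil protease genes Elane and Ctsg were 275-fold (49.3 to 10880) and 158-fold (28.3 to 6260) higher, each from 1 control UMI, in a library with 260 neutrophil-like cells against 19 in the control. Wfdc2 was 21.2-fold higher in these cells, and Pga5 27.5-fold, Muc5b 27.9-fold, Tff1 23.2-fold and Bpifb1 21.99-fold lower, with Atp4a 418-fold (73.6 to 16620) lower from 1 YAP5SA UMI. The matrix cytokine gene Spp1 was 24.9-fold (17.6 to 36.5) higher. Inflammatory list medians were above 0 in all YAP5SA classes read, from 0.44 in macrophage-like to 1.21 in glia-like cells. The list includes Lcn2 and Cxcl5, leading genes of the YAP5SA epithelial subcluster 12. Epithelial RNA was also found in these classes, with Wfdc2 at 153 against 9.14 CPM in glia-like cells, so these medians cannot be ascribed to the cells themselves.

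In Yap knockout fibroblast-like cells, the acute-phase gene Saa3 was 58.9-fold (37.1 to 98.6), the collagen gene Col6a4 21.5-fold (17.4 to 26.7) and the transcription factor gene Dach1 9.04-fold (7.25 to 11.3) higher. Ghrl was 10.7-fold and Cmss1 5.47-fold higher in the same cells. Clec3b, the tetranectin gene, was 7.50-fold (6.57 to 8.60), the hyaluronan synthase gene Has1 3.56-fold, the secreted protein gene Cthrc1 3.00-fold, S100a16 3.05-fold and the protease gene Mmp23 2.97-fold lower. Smooth muscle-like cells had Ghrl 7.55-fold, Cmss1 5.27-fold, Sncg 4.07-fold, Leng9 4.06-fold and Apoa4 4.05-fold higher, and the matrix genes Dpt 10.0-fold, Mfap5 5.77-fold and Col14a1 5.13-fold lower, with Plac9 4.28-fold and Rabgef1 4.05-fold. Dpt, Mfap5 and Plac9 were leading genes of a fibroblast-like cluster, and Col1a1 stood at 1930 CPM against 5858 in the smooth muscle-like cells. These cells also lay mostly in cluster 17 in the Yap knockout and cluster 8 in the control. The lower values of those 3 genes therefore cannot be ascribed to the muscle cells themselves. In macrophage-like cells the cytokine gene Il1b stood at 1823 CPM against 280, 6.50-fold (6.002 to 7.05) higher, in a class with 179 cells from cluster 22 and 224 from cluster 6, against 68 and 324 in the control, with Apoa4 5.24-fold, Flrt3 5.03-fold, Ddit4 4.28-fold and Tnip3 3.77-fold higher. The arginase gene Arg1 was 41.0-fold (17.2 to 128) lower in them, and Col1a1 9.91-fold, Plac9 7.63-fold, Col1a2 7.15-fold and Dlk1 6.90-fold, next to the smaller share of fibroblast-like cells. Intestinal list medians stood between 0.79 and 1.27 in the non-epithelial classes read, next to the intestinal genes of the epithelium. Endothelial-like cells were not compared, since the control held 194 of them.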

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

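All tests given in this part were chosen after the result was seen, except the subtraction of stromal RNA and the removal of neighbouring-region cells for the last pattern, whose outcomes were written down before they were computed (the settings themselves were added after the first look at the data, and the reading that a median over fewer members decides nothing after the values were seen).

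A stromal cluster that met no marker name held 2011 of 8518 YAP5SA cells, 23.6% (22.7 to 24.5), against 5 of 6959 control cells (0.0718%) and 0 of 4890 Yap knockout cells, which allows a share of up to 0.0613%. It stood out as a large group of cells without a class name, which the comparisons by class leave out and the non-epithelial sums include. The naming rule tried it as interstitial cell of Cajal, from 1 leading marker and a mean marker log2 fold of 0.035. Fibroblast was the next class, with a mean marker log2 fold of 1.195, but the rule tried no further class. Its absence from the fibroblast-like class thus depends on that rule. Cells of the cluster carried collagen at a lower level than the fibroblast-like cells of the same library (Col1a1 at 8398 against 15030 CPM) and high levels of Wnt feedback genes, with the secreted Wnt inhibitor gene Notum at 183 against 12.6 CPM. A shift of the whole YAP5SA library is argued against, since 89.1% of YAP5SA cells in the other non-epithelial classes lay in clusters with at least 10% control cells, the exceptions being neutrophil-like (0%) and erythroid (37.7%) cells. Doublets with, or free RNA from, the epithelium are argued against as well, since epithelial markers stood at 0.980 times their level in YAP5SA fibroblast-like cells. A stromal layer released by the dissociation of this tissue alone cannot be told apart from a cell state that the control lacks, because the share of 23.6% is 1 value from 1 library, so both stay open, the genotype among them as an untested explanation.

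The far lower level of gastric secretory genes in the YAP5SA epithelium was set against 3 technical explanations. Squamous forestomach taken in place of glandular epithelium was tested by the squamous markers. Outside the squamous-like subcluster they stood at a median of 3.21% of their level in it. This cannot decide, since the subcluster was named by the same markers and removed first. Squamous-like cells were 9.88% of YAP5SA and 2.21% of control epithelial-like cells, so most YAP5SA epithelial-like cells were not squamous-like by these markers. Without squamous-like and intestinal-like cells the squamous list median was 1.90, over fewer genes than the median of 0.79 in all epithelial-like cells. Squamous genes were also above the control in YAP5SA non-epithelial classes, so the value of 1.90 decides nothing. A larger part of forestomach in the YAP5SA library stays open. For dilution by RNA of other cells or lower depth, the broad epithelial markers had a median log2 ratio of 0.845, higher in YAP5SA. Most YAP5SA epithelial-like cells were named by these same markers, which limits that test. Dilution is argued against by a median depth of 6268.5 UMIs in YAP5SA and 2474 in the control. Measured by collagen, RNA of other cells was up to 28.5% of the YAP5SA epithelial sum and 44.5% of that of the control. Over the mesothelial markers the median was 2.14% of the mesothelial-like level, although Msln itself stood at 140% and Upk1b at 59.3% of that level. By these markers most YAP5SA epithelial-like cells were not mesothelial-like. The same markers had been used in naming the clusters, so mesothelial cells counted as epithelial are not decided independently of the naming. With dilution argued against, forestomach left open and mesothelial cells not decided independently of the naming, an effect of the YAP5SA genotype on the epithelium is a hypothesis. It may hold, but was found and tested on the same 3 libraries and without a replicate.

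The YAP/TEAD median was lower in the Yap knockout epithelium (-0.29). Cells of neighbouring gut regions in the control are argued against, since the median was -0.25, still below that interval, without squamous-like and intestinal-like cells. Collagen in the epithelial sum stood at 7770 CPM in the control and 1072 CPM in the knockout, so RNA of stromal cells differs as well. With it subtracted, though only in part since Col1a1 still stood at 911.5 against 75.95 CPM, the median was -0.10, inside the interval of matched random lists. Only 11 of 18 members were still measured, 8 lower and 3 higher. Ccn1, Amotl2, Myof, Nt5e and Ptpn14 lay further below the control than before, and Crim1 and F3 moved from above it to -0.07 each. Ccn1 stood at -1.16, Amotl2 at -1.04 and Ptpn14 at -0.73, and the higher members Gadd45b, Amotl1 and Dock5 at 0.98, 0.32 and 0.28, whereas Ccn2, Igfbp3, Lats2, Rbms3 and Tgfb2 were reduced to 0 in both libraries. Stromal RNA and loss of YAP activity in the knockout epithelium therefore cannot be told apart and both stay open, the latter untested.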

How the results depend on the processing

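Of the tests in this part, those without squamous-like and intestinal-like cells, without cycling-like cells, without low-count subclusters, without the fixed genes, with doublets placed and with non-epithelial RNA subtracted were chosen after the result was seen. No paired analysis was possible because each genotype has 1 library and the only number the libraries share is replicate 1. Counting error is the only error that can be read, depth limits genes under about 10 CPM, and the marker-gate alternative gave no value because it left 0 control, 9 YAP5SA and 110 Yap knockout cells. Of the gene lists with a median, 27 of 28 in YAP5SA and 15 of 29 in the Yap knockout kept their direction under every alternative. For the values below the cause was not tested, except where a clause names it. The YAP/TEAD medians ranged from 0.67 to 2.69 in YAP5SA and from -0.34 to -0.02 in the Yap knockout, the pit medians from -2.15 to -1.71 and from -0.36 to 0.29, and the DNA replication medians from 0.15 to 1.54 and from -0.36 to -0.06. The values of 0.67 and 0.15 came from keeping doublets, where the main YAP5SA epithelial cluster was left out.

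With TMM scaling the YAP5SA medians were 1.28 for YAP/TEAD targets, -1.71 for pit genes and 0.94 for DNA replication. With at least 1000 detected genes the knockout pit median was 0.28, the epithelial-like share was 11 points above the control in YAP5SA and 11.6 in the knockout (the reported values are 7.5 and 14.4), and the pit-like share differed by -13.1 and -3.7 points (reported -17.9 and -8.9). With at most 10% mitochondrial UMIs these were 0.29, 10.6, 7.7, -12.2 and, reversed, 2.0. At resolution 0.5 the YAP5SA pit-like difference was -24.9 points, with each library clustered alone -14.5, and without the fixed genes -53.3, with -45.2 in the knockout.

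With doublets kept, the main YAP5SA epithelial cluster lost its name through the naming rule. It was tried as mesothelial from 1 leading marker, with a mean marker log2 fold of -0.165 against 2.16 for epithelial markers. Its 1605 YAP5SA cells were thus left out, and 315 stayed epithelial-like, 196 of them squamous-like. With those cells left out, the YAP/TEAD median was 0.67, DNA replication 0.15, and, reversed, Yap1 -0.01 and the epithelial-like difference -9.9 points. With the doublets placed in the existing clusters, all 10 values stayed within counting error. As a mean over cells the knockout pit median reversed to -0.36, DNA replication in YAP5SA was 0.70 and Yap1 in the knockout -0.67 (reported -0.89). Thinned to 2000 UMIs, which left out 384 control, 300 YAP5SA and 520 knockout cells, the knockout values were -0.02 for YAP/TEAD targets, -0.25, reversed, for pit genes and -0.47 for Yap1, and the YAP5SA values -1.71 for pit genes and 0.73 for DNA replication. A pseudocount of 1 without the low-level filter gave -2.10 for pit genes in YAP5SA.

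Without squamous-like and intestinal-like cells the YAP5SA pit median was -2.15, and without cycling-like cells DNA replication in YAP5SA 0.55. Without low-count subclusters it was -1.95, the knockout pit median 0.29 and the YAP5SA pit-like difference -22.9 points. With non-epithelial RNA subtracted the YAP5SA medians were 2.69, -2.03 and 1.54 for YAP/TEAD, pit and DNA replication genes, and the knockout values -0.10, -0.07 (reversed) and -0.06, with Yap1 at -1.35. Of the other knockout lists, subtraction reversed gastric transcription factors to -0.08, Notch to 0.01, adhesion to 0.11, actin to 0.34 and dissociation stress to 0.14, and thinning reversed Notch to 0.03 and adhesion to 0.02. In the largest shared subclass, the neck-like cells (98, 10 and 299), 35 of 40 named genes kept their direction; reversed were Anxa8 at -0.71, Upk1b at -0.71 and Tff1 at 0.64 in YAP5SA, and Gast at -1.19 and Rbp2 at -0.53 in the knockout.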

Other observations

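The values in this part belong to no comparison planned at the outset, and the genes of the unnamed cluster and the genes of the last paragraph were chosen after their values were seen.

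The stromal cluster found in YAP5SA carried a set of Wnt-response and extracellular genes. Besides Notum, the Wnt inhibitor gene Apcdd1 stood at 152 CPM there, 22.1 in YAP5SA fibroblast-like cells and 10.2 in control fibroblast-like cells. The feedback gene Axin2 stood at 29.6, 6.01 and 5.20 CPM and the transcription factor gene Lef1 at 31.1, 4.81 and 0.985. The growth factor binding protein gene Igfbp3 stood at 1062, 341 and 94.7 CPM, the tachykinin gene Tac2 at 173, 10.4 and 0.875, and the matrix protease gene Mmp2 at 703, 237 and 269. Joined with this cluster, YAP5SA fibroblast-like cells had a Wnt target median of 0.47 (percentile 100) against 0.15 (percentile 91.6) alone. Wnt7b, which stood at 114 CPM in the YAP5SA epithelium, is a ligand of the same pathway, but a link between it and the stromal cluster was not tested.

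Some gene groups differed between compartments of the same library. Cholesterol synthesis genes were above the control in the YAP5SA epithelium and below it in each of the other YAP5SA classes read, from -0.23 in interstitial cells of Cajal to -0.63 in enteric glia-like cells. YAP/TEAD targets had a median of 0.52 in Yap knockout fibroblast-like cells (16 of 19 higher, percentile 99.9). Interferon genes stood at 0.66 in Yap knockout fibroblast-like cells (percentile 99.9). That class held 299 cells of cluster 0 and 226 of cluster 4 in the Yap knockout, against 1403 and 1784 in the control. A different mix of clusters was not separated from a change within the cells for either list. In Yap knockout macrophage-like cells YAP/TEAD targets stood at -0.61 (14 of 16 lower, percentile 0.07) and Wnt targets at -1.15 (7 of 7 lower, percentile 0.02), next to free stromal RNA that was lower as well, with collagen and matrix genes at -1.98 and Col1a1 at 445 CPM against 4414, so neither value can be ascribed to the macrophages. Squamous genes stood between 1.06 and 1.46 in the YAP5SA non-epithelial classes, next to the keratins of the epithelium.

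Among YAP5SA epithelial-like cells, 36 lay in the gastric subclusters 0 to 2 with 614 control cells. These carried Tff1 at 3061 CPM and Pga5 at 12720, against 8440 and 20900 in the control cells of the same subclusters, and Ccn2 at 11.9 against 12.5, from 2 UMIs. Msln stood at 161 against 30.8 CPM and Wfdc2 at 752 against 356 in the same cells, where non-epithelial cells had Msln at 83.9 against 28.8 and Wfdc2 at 148 against 24.8. Ankrd1 and Wnt7b, with 2 UMIs each, stood at 11.9 against 0 and 0.872.

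Xist, the X-inactivation transcript, stood at 157 CPM in the control epithelium, 0.225 in YAP5SA and 361 in the Yap knockout, and at 102, 0.350 and 300 CPM in non-epithelial cells. The Y-linked gene Ddx3y stood at 49.2, 65.4 and 40.1 CPM in the epithelium. The control and Yap knockout libraries thus held RNA of both sexes and the YAP5SA library almost none of the Xist transcript, so sex is confounded with genotype. Cmss1 was 4.11-fold and Camk1d 4.55-fold higher in the Yap knockout epithelium, and both were also higher in its non-epithelial cells, Cmss1 at 4109 CPM against 857 and Camk1d at 1698 against 535.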
